A study of Mus musculus with 36 samples.

How the data were processed

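Hepatic stellate cells, liver sinusoidal endothelial cells and hepatocytes were each measured by bulk RNA sequencing in 4 WT libraries, 4 libraries taken 12 h and 4 taken 36 h after diphtheria toxin, 36 libraries in all. The deposited files hold read counts per gene for 24421 gene symbols, 1 file per library, with 5 further lines on reads in no gene, ambiguous reads and reads left uncounted for other reasons. Per the submitters' processing notes, the authors checked reads with FastQC 0.11.4, trimmed them with Trimmomatic 0.35, mapped them to mm10 with TopHat2 2.1.0 and used SAMtools 0.1.18. The counting tool, its strand setting and the gene annotation are not given in the sources used here, and a read that fits several genes of a family is not assigned by any rule known here. Totals of 25.4 to 31.7 (in units of 1000000 counts) per library set the precision, with 4.9 to 9.02% of reads in no gene and 12632 to 14848 genes with a count. No 2 of the 54 pairs of libraries within a group were identical. Floors and their bounds cover counting error only, since the reads carry no molecular identifiers that are used here.

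Counts were tested per gene with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), with TMM scaling, the filterByExpr filter by group (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment, an adjusted p under 0.05 counting as called. Each cell type had its own fit of 3 groups, the WT comparison of cell types used the 12 WT libraries, and the difference between responses used all 36 libraries in 1 fit with 9 groups. The standard error given with a log2 fold is the absolute log2 fold divided by the square root of the F statistic. CPM values are counts per 1000000 on TMM-scaled library sizes, scaled within a cell type except for the WT comparison of cell types, where scaling ran over the 12 WT libraries, so the level of 1 gene in the same libraries differs between these (Alb in hepatocyte WT libraries at 46512 and 32817 CPM) and is compared only within each. A fold against a group with no counts is given as a bound from a floor of 3 counts over the group. Genes were placed on GRCm38 (mm10) with the RefSeq annotation by symbol. The 26 gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01 when at least 5 members were tested, adjusted over 189 tests of lists. They cover chemokines, leukocyte adhesion molecules, macrophage niche ligands, Notch targets, BMP and SMAD targets, NF-kB response, STAT3 response, interferon-stimulated genes, acute phase proteins, sterol biosynthesis and LXR targets. They also cover bile acid and drug metabolism, iron handling, stellate cell activation, angiocrine and vascular growth factors, cell cycle, immediate early and heat shock genes, p53 targets and the identity of the 3 cell types. Others hold markers of Kupffer cells, monocytes and neutrophils, lymphocytes, cholangiocytes, and erythroid cells and platelets. For each list the calls were also adjusted over the list alone.

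Groups, comparisons, tests, lists and the rule for naming genes were set before the data were examined. By that rule the text draws, for each comparison with WT, on the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups, leaving out gene models and pseudogenes. It also draws on 15 genes given in every cell type where they were tested (among them Ccl2, Ccl7, Cxcl1, Cxcl10, Vcam1, Icam1, Sele, Selp, Csf1, Il34, Dll1, Dll4, Tgfb1 and Abca1) and on up to 4 called members of each list by smallest adjusted p. From the lists of cell identity and other cells it takes up to 4 members with a mean of at least 1 CPM by level, from the change between 12 h and 36 h and from each response difference the 5 largest each way, and from the WT comparison the niche ligands and identity genes. From these, genes that kept their call in every alternative were preferred, and genes outside the rule are named as chosen after their values were seen. The alternatives tried were RLE scaling, no filter on low counts, DESeq2 1.42.0, a fit of only the 2 groups compared, replicate number as a block, camera with an estimated correlation and fry for lists, and leaving out each library in turn. Added after seeing the data were the split of hepatocyte libraries at 100 CPM of Malat1, as a term and within each side. So were a term for animals that HSC and LSEC libraries of 1 number would share, in a fit without hepatocyte libraries. Fits without replicate 3 at 12 h and replicate 4 at 36 h were added then too.

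The test was tried on simulated data with 200 changed genes per comparison, and edgeR recovered 41.8 to 73.1% of 2-fold changes in the 6 comparisons with WT, with 0.794 to 7.87% of its calls false. DESeq2 made 8.72 to 22.1% false calls on the same data, and in hepatocytes edgeR recovered 4.48% of 1.5-fold changes at 12 h and 2.99% at 36 h. Each count of genes or lists was set against all 35 divisions of the 8 libraries into groups of 4, and counts from fits of 3 cell types against 100 drawn regroupings. Outlying libraries were sought with Dixon's ratio in each group of 4 (limit 0.829), for library totals, list scores (the mean log2 CPM of a list's members) and each gene whose group values are printed. Permutation tests were run in R and figures drawn in Python 3.11.15 with matplotlib 3.10.9. Replicate numbers are shared between groups, and libraries of 1 number were taken as pairs only where every correlation of their deviations from the group means passed 0.1. This held for hepatocytes at 36 h against WT (0.42 to 0.53), a pairing found in the data and not stated in the labels. The main count for that comparison still comes from the fit without pairs. No library was left out of the values given in the text.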

Results

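RNA was sequenced from 3 cell types of the liver of C57BL/6 mice. Hepatic stellate cells (HSCs) are the vitamin A-storing cells around the sinusoids, liver sinusoidal endothelial cells (LSECs) line these capillaries, and hepatocytes are the parenchymal cells. Each cell type had a WT group, described by the series as mice given PBS, and groups taken 12 h and 36 h after an injection of diphtheria toxin (DT). In the study the toxin serves to remove Kupffer cells, the resident macrophages of the liver, and the comparisons ask how the 3 neighbouring cell types answer that loss. The 9 groups held 4 libraries each, 36 in all. Gene counts per library, in units of 1000000, ran from 25.9 to 31.7 in HSC WT, 25.7 to 28.9 in HSC 12 h and 27.5 to 29.7 in HSC 36 h. They ran from 27.5 to 30.1 in LSEC WT, 26.2 to 29.4 in LSEC 12 h and 25.4 to 29.7 in LSEC 36 h, and from 27.1 to 30.3 in hepatocyte WT, 28.6 to 30.6 in hepatocyte 12 h and 26.2 to 30.6 in hepatocyte 36 h. Levels below are counts per 1000000 (CPM) on TMM-scaled library sizes, as mean ± SD over the libraries of a group (n = 4). No group analysed here received the toxin while keeping its Kupffer cells, so an effect of the toxin itself is not separated from an effect of the depletion. The labels give the same strain for every library and no genotype, so a difference in genotype between PBS and toxin mice is not separated from the depletion either. The labels do not say that each library is 1 mouse, so each p-value measures spread between libraries.

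The summed RNA of most Kupffer cell markers was low in every cell type and lower on average after the toxin. The summed level of 11 Kupffer cell markers, a list that leaves out the C1q genes and Fcna, was 9.49 ± 5.82 CPM in HSC WT libraries, 1.36 ± 1.51 at 12 h and 5.07 ± 6.92 at 36 h. In LSECs the sum was 20.9 ± 7.20, 3.65 ± 1.62 and 8.60 ± 7.38 CPM, and in hepatocytes 14.2 ± 6.82, 5.06 ± 2.43 and 4.41 ± 1.63 CPM. At 36 h replicate 4 held the highest sum in both HSCs (15.4 CPM against 1.19 to 1.83) and LSECs (18.8 CPM against 1.97 to 9.01), so the higher means at 36 h than at 12 h rest largely on that library. The C1q genes and Fcna were left out after their values were seen. With all 15 members the sum was 2263 ± 715, 1933 ± 336 and 1638 ± 480.2 CPM in HSCs, 50.2 ± 17, 59.7 ± 20.7 and 43.8 ± 36.5 in LSECs and 19.2 ± 11.9, 5.17 ± 2.47 and 4.67 ± 1.51 in hepatocytes, so in LSECs it was not lower at 12 h. Cd5l, a secreted protein of Kupffer cells, fell from 6.51 ± 3.25 to 0.0557 ± 0.0899 CPM in LSECs at 12 h (log2 fold change -6.79 ± 1.23 SE, adjusted p = 0.0025). In HSCs it fell from 3.01 ± 2.27 to 0.0463 ± 0.0559 CPM (log2 fold change -5.92 ± 1.45 SE, adjusted p = 0.0072). Timd4, a receptor for dying cells on resident macrophages, had 0.910 ± 0.381 CPM in LSEC WT libraries and no count in the 4 LSEC libraries at 12 h. That is at least 33.5-fold lower, with a floor of 3 counts over the group.

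**Figure D1:**
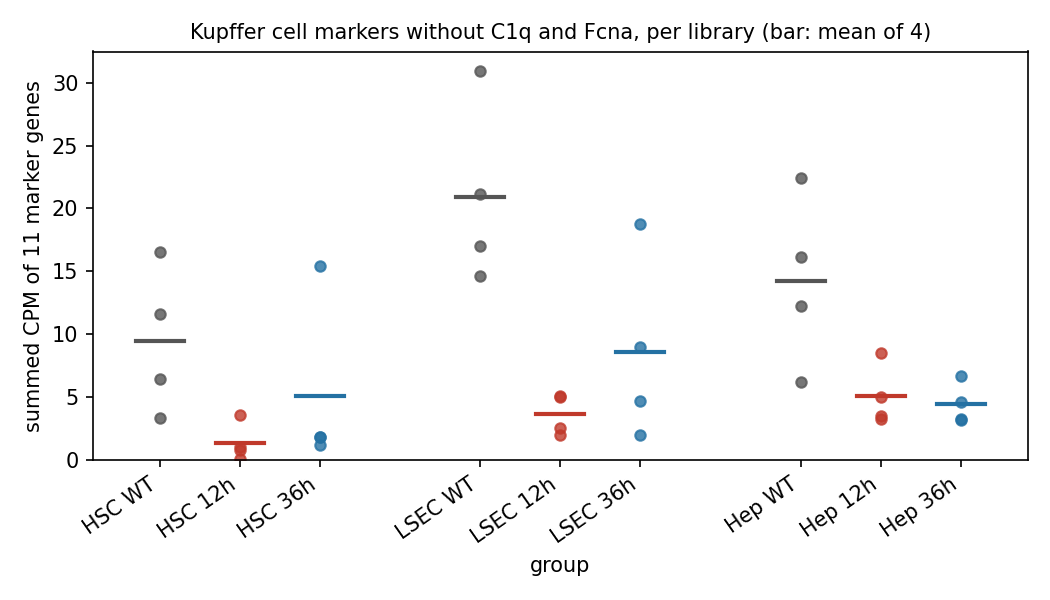
Summed level of the 11 Kupffer cell markers (CPM, linear axis) in each library, by cell type and group, with a bar at the mean of 4 libraries. LSEC libraries run from 14.6 to 31 CPM in WT and from 1.99 to 5.05 CPM at 12 h.

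The WT libraries show which of the 3 cell types makes each signal of the macrophage niche. Gdf2, which encodes BMP9, stood at 2455 ± 148 CPM in HSCs, 0.580 ± 0.504 in LSECs and 0.132 ± 0.228 in hepatocytes. Bmp10, its closest relative, stood at 135 ± 14.2 CPM and Bmp5 at 645 ± 42.9 CPM in HSCs, and both were under 1 CPM in LSECs. The macrophage growth factor Csf1 stood at 447 ± 58.6 CPM in HSCs, 239 ± 38 in LSECs and 4.17 ± 1.07 in hepatocytes. Il34, the other ligand of its receptor, stood at 266 ± 45.4 CPM in HSCs and 0.122 ± 0.102 in LSECs. LSECs held the Notch ligands Dll4, at 36.6 ± 8.81 CPM in HSCs, 424 ± 74.0 in LSECs and 0.144 ± 0.206 in hepatocytes, and Dll1, at 40.3 ± 14.8 CPM against 0.378 ± 0.274 in HSCs. HSCs held Jag1, at 110.9 ± 17.3 CPM against 14.9 ± 4.56 in LSECs. Tgfb1, Bmp2 and Bmp6 were likewise highest in LSECs, at 217 ± 22, 2210.5 ± 685 and 446 ± 130.4 CPM against 91.9 ± 8.72, 196 ± 13.2 and 1.19 ± 0.477 in HSCs. Gas6, a ligand of the receptors that clear dying cells, stood at 2.75 ± 0.668 CPM in HSCs, 547 ± 82.5 in LSECs and 111.5 ± 42.0 in hepatocytes. In edgeR's quasi-likelihood fit of the 12 WT libraries, with Benjamini-Hochberg adjustment, 9 of 20 niche ligands were highest in HSCs, 8 in LSECs and 1, Bmp7, in hepatocytes at 2.73 ± 1.29 CPM. The remaining 2, Inhba and Pros1, had no cell type above both others.

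Identity genes marked the 3 preparations. Lrat, which esterifies vitamin A, stood at 2907 ± 392.3 CPM in HSCs and 0.921 ± 0.466 in LSECs. The scavenger receptor gene Stab2 stood at 4.0 ± 1.82 CPM in HSCs, 4445 ± 632 in LSECs and 8.54 ± 2.36 in hepatocytes. Alb, for serum albumin, stood at 162 ± 33.1 CPM in HSCs, 58.8 ± 29.7 in LSECs and 46512 ± 10494 in hepatocytes. Of all 13389 genes tested, 2348 were highest in HSCs, 2480 in LSECs and 3971 in hepatocytes. Of the identity lists, 19 of 20 stellate cell genes, 20 of 20 LSEC genes and 20 of 20 hepatocyte genes were highest in their own cell type.

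**Figure D2:**
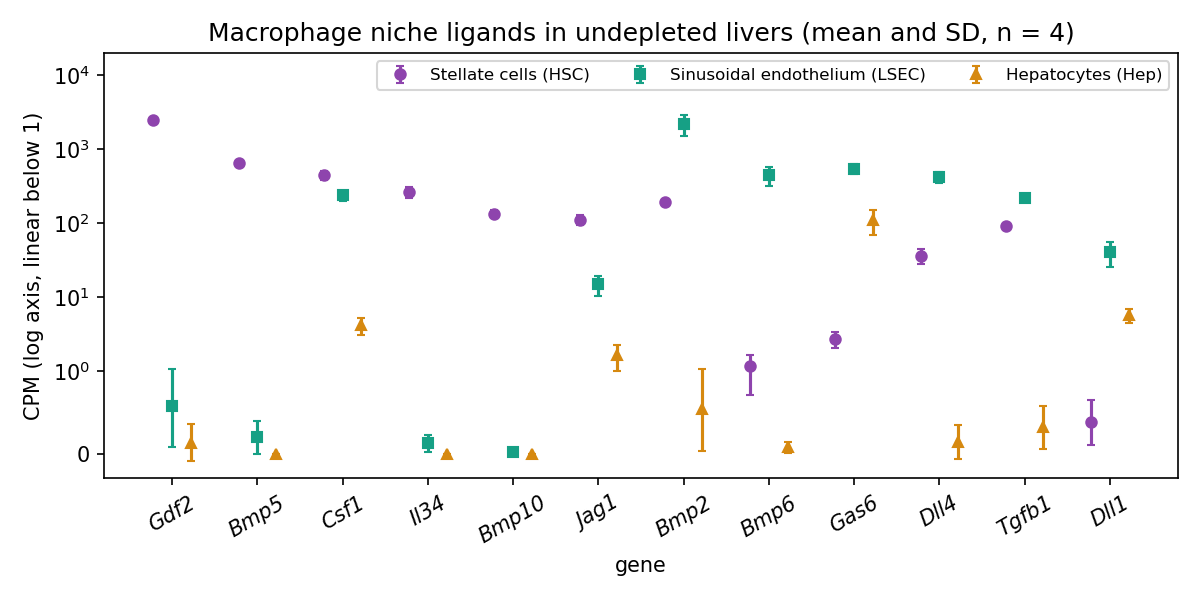
Level of 12 niche ligands (CPM, symmetric log axis, linear below 1) in WT HSCs, LSECs and hepatocytes, as mean with SD of 4 libraries. Gdf2 reaches 2455 CPM in HSCs and Dll4 424 CPM in LSECs.

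Several genes that recruit leukocytes rose in HSCs within 12 h of the toxin. Ccl2 (chromosome 11, 82035577 to 82037452, mm10), the main chemokine for CCR2-bearing monocytes, rose from 71.0 ± 16.6 to 1395 ± 599 CPM (log2 fold change 4.30 ± 0.46 SE, adjusted p = 5.16e-05). All 4 of its libraries lay above every WT library. The neighbouring gene Ccl7, which acts on the same receptor, rose from 5.70 ± 0.670 to 213 ± 144 CPM (log2 fold change 5.22 ± 0.66 SE, adjusted p = 0.00013). The neutrophil attractants Cxcl1 and Cxcl5 rose from 6.75 ± 2.52 to 118 ± 84.0 CPM and from 0.504 ± 0.219 to 208 ± 162 CPM (log2 fold 4.13 and 8.69). Ccl19, a ligand of CCR7, rose from 23.0 ± 4.0 to 489 ± 302 CPM. The interferon-induced Cxcl10 rose from 33.5 ± 11.4 to 355 ± 216 CPM, and Cxcl16, a membrane-bound ligand of CXCR6, from 104 ± 4.67 to 406 ± 98.1 CPM. Among adhesion molecules, Vcam1 (chromosome 3, 116110020 to 116129688), which holds rolling monocytes through integrin VLA4, rose from 461 ± 94.2 to 2372 ± 650.5 CPM (log2 fold change 2.36 ± 0.22 SE, adjusted p = 2.25e-05). Icam1 rose from 186 ± 17.1 to 559.7 ± 174 CPM and the selectin gene Sele from 1.23 ± 0.485 to 133 ± 80.7 CPM. Among chemokines, 12 of 17 rose and 3 fell (13 and 3 adjusted over the list alone). Among leukocyte adhesion molecules, 5 of 12 rose and 4 fell (5 and 4 adjusted over the list alone). The adhesion list did not pass camera (adjusted p = 0.555). The summed level of all chemokines of the list was 11931 ± 551 CPM in WT and 8379.7 ± 924 at 12 h, so the sum did not rise with them. Such a sum follows its most abundant members and does not describe the 12 of 17 that rose.

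Niche ligands of HSCs went both ways at 12 h. Csf1 (chromosome 3, 107741048 to 107760469) rose from 509 ± 67 to 1195 ± 321 CPM (log2 fold change 1.23 ± 0.17 SE, adjusted p = 0.00025). Il34 rose from 303 ± 51.2 to 458 ± 75.8 CPM (log2 fold change 0.60 ± 0.16 SE, adjusted p = 0.0135), and Bmp2, a relative of BMP4, rose from 224 ± 15.2 to 594 ± 213 CPM (log2 fold 1.41). Bmp5 fell from 735 ± 49.0 to 447 ± 86.4 CPM and Pros1, for protein S, a bridge to dying cells, fell from 996 ± 45.7 to 623 ± 163.2 CPM (log2 fold -0.72 and -0.68). Dll4 had 41.7 ± 9.93 CPM in WT and 47.1 ± 18 at 12 h (adjusted p = 0.617), and Tgfb1 105 ± 9.92 and 146 ± 46.6 (adjusted p = 0.0558). Hey1, a repressor downstream of Notch, fell from 12.9 ± 2.41 to 6.40 ± 2.01 CPM and Angpt1, the ligand of Tie2, from 36.3 ± 2.21 to 9.50 ± 4.02 CPM. Among niche ligands, 4 of 17 rose and 6 fell (6 and 7 adjusted over the list alone). Their median log2 fold was -0.23 and their mean 0.12. Camera's direction was down, but the list did not pass camera (adjusted p = 0.8). Among Notch targets, 4 of 6 fell (4 adjusted over the list alone). Among BMP and SMAD targets, 2 of 11 rose (0 adjusted over the list alone). Among angiocrine growth factors, 1 of 9 rose and 2 fell (1 and 2 adjusted over the list alone). Their median log2 fold was 0.10 and their mean -0.07. Camera's direction was down, but the list did not pass camera.

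**Figure D3:**
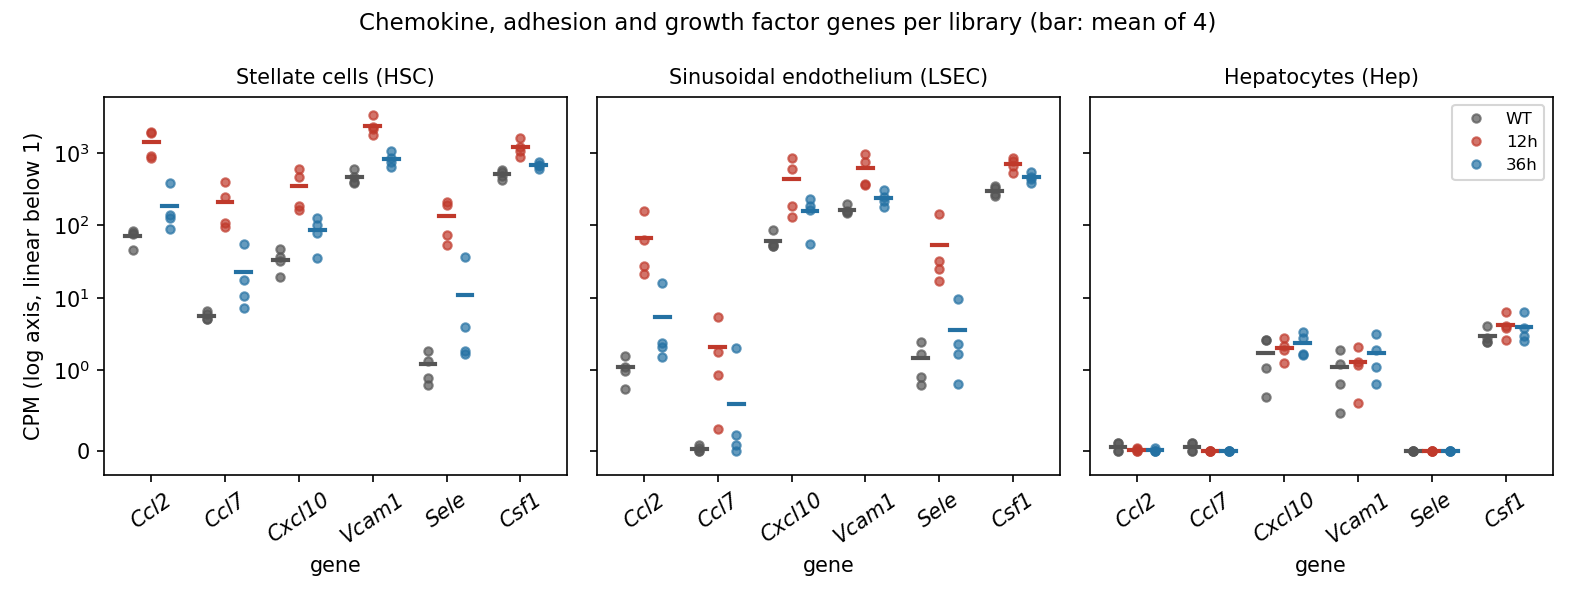
Level of Ccl2, Ccl7, Cxcl10, Vcam1, Sele and Csf1 (CPM) in each library of the 3 cell types, with a bar at the mean of 4 libraries. In HSCs, Ccl2 has a mean of 71.0 CPM in WT, 1395 at 12 h and 185 at 36 h.

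Acute phase genes were among the largest rises in HSCs at 12 h, beside a protease, chemokines and a selectin. Saa3, an apolipoprotein of inflammation, rose from 0.144 ± 0.133 to 162.9 ± 253 CPM (log2 fold change 10.16 ± 1.46 SE, adjusted p = 0.000276). The iron-siderophore binder Lcn2 rose from 0.124 ± 0.105 to 75.6 ± 102 CPM (log2 fold change 9.16 ± 1.16 SE, adjusted p = 0.000136). Timp1, an inhibitor of matrix proteases, rose from 2.08 ± 0.731 to 131 ± 43.8 CPM. The metallothionein gene Mt2 rose from 9.78 ± 3.08 to 219 ± 48.6 CPM and Cp, for ceruloplasmin, from 439 ± 56.9 to 1102 ± 198 CPM. Adamts8, a secreted protease, had no count in the WT libraries and 6.45 ± 2.94 CPM at 12 h. That is at least 251-fold higher, with the same floor. Sod2, the mitochondrial superoxide dismutase induced by NF-kB, rose from 94.9 ± 5.54 to 544 ± 190.5 CPM and Nfkb2 from 40.4 ± 5.71 to 189.9 ± 48.5 CPM (log2 fold 2.52 and 2.23). The interferon-induced GTPase gene Gbp2 rose from 99.1 ± 11.8 to 973 ± 235 CPM and the nucleic acid sensor gene Zbp1 from 23.1 ± 6.71 to 172 ± 70.3 CPM. Hmox1, which degrades heme, rose from 9.66 ± 0.655 to 27.8 ± 7.54 CPM, and Hsph1, a heat shock protein, from 34.5 ± 18.6 to 102 ± 55.4 CPM. Among NF-kB response genes, 20 of 22 rose (21 adjusted over the list alone). Among STAT3 response genes, 11 of 15 rose (12 adjusted over the list alone). Among interferon-stimulated genes, 28 of 30 rose (29 adjusted over the list alone). Among acute phase proteins, 19 of 23 rose (21 adjusted over the list alone). Among immediate early and heat shock genes, 12 of 21 rose (13 adjusted over the list alone). Among iron handling genes, 4 of 14 rose and 2 fell (6 and 2 adjusted over the list alone). Among p53 targets, 4 of 12 rose and 1 fell (6 and 1 adjusted over the list alone). The summed level of the immediate early and heat shock genes ran from 3874 to 13492 CPM in WT and 7999 to 25048 at 12 h, highest in WT replicate 2 and in 12 h replicates 1 and 4. How reads that match both Saa1 and Saa2, or several Serpina3 genes, were counted is not known.

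Matrix, lipid and identity genes of HSCs changed in both directions at 12 h. Col1a1, a chain of type I collagen, rose from 306 ± 29.3 to 567 ± 40.05 CPM (log2 fold change 0.89 ± 0.14 SE, adjusted p = 0.00042). The gelatinase gene Mmp2 fell from 285 ± 29.3 to 79 ± 25.4 CPM (log2 fold change -1.85 ± 0.22 SE, adjusted p = 8.47e-05). Colec11, a collectin of complement, fell from 4744 ± 201 to 2266 ± 696 CPM (log2 fold -1.07), and Reln, for reelin, had 5411 ± 1276 and 4057 ± 1526 CPM (adjusted p = 0.328). Among the 10 largest falls were Crygs, a crystallin, from 11.5 ± 2.26 to 0.338 ± 0.343 CPM, and Sptssb, a subunit of the enzyme that starts sphingolipid synthesis, from 11.4 ± 4.40 to 0.508 ± 0.456 CPM. Cd83, an immunoglobulin-family receptor, fell from 9.70 ± 2.14 to 0.828 ± 0.653 CPM and Ackr4, a scavenger of CCL19 and CCL21, from 12.8 ± 4.55 to 1.14 ± 0.953 CPM. Srebf2, the regulator of sterol synthesis, rose from 70.5 ± 8.56 to 111.5 ± 17.8 CPM. Cyp7b1, an oxysterol hydroxylase, rose from 0.332 ± 0.112 to 5.18 ± 3.01 CPM. Among stellate activation genes, 6 of 19 rose and 2 fell (6 and 2 adjusted over the list alone). Among stellate identity genes, 4 of 20 rose and 8 fell (4 and 8 adjusted over the list alone). Among sterol biosynthesis genes, 9 of 24 rose and 1 fell (9 and 1 adjusted over the list alone). Among LXR targets, 3 of 12 rose and 1 fell (3 and 1 adjusted over the list alone). Among bile acid and drug metabolism genes, 1 of 20 rose and 2 fell (1 and 1 adjusted over the list alone). Among cell cycle genes, 1 of 28 rose and 1 fell (0 and 0 adjusted over the list alone).

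Markers of other cells went different ways in HSCs at 12 h. Alb stood at 185 ± 37.8 CPM in WT and 178 ± 38.1 at 12 h. Tek, the Tie2 receptor of endothelial cells, fell from 35.5 ± 11 to 8.90 ± 0.670 CPM. Plac8, a gene of several blood cell types, rose from 287 ± 40.6 to 746 ± 256 CPM and Pf4, a platelet chemokine, from 12.8 ± 2.08 to 60.2 ± 14.1 CPM. Hepatocyte identity had 0 of 19 called by edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by DESeq2). Among Kupffer cell markers, 7 of 10 fell (7 adjusted over the list alone). Among LSEC identity genes, 2 of 18 rose and 3 fell (1 and 3 adjusted over the list alone). Among monocyte and neutrophil markers, 1 of 3 rose and 1 fell (1 and 1 adjusted over the list alone), with a median log2 fold of 0.06 and a mean of -0.04. Among erythroid and platelet markers, 1 of 3 rose (1 adjusted over the list alone), with a median log2 fold of -0.01 and a mean of 0.68. Cholangiocyte markers had 0 of 1 called by edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by DESeq2). No lymphocyte marker passed the count filter, and these markers set no limit on RNA of blood cells.

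Across the 12676 genes tested in HSCs, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4060 at 12 h, 2150 higher and 1910 lower, of which 685 and 631 changed at least 2-fold. The 4 libraries at 12 h lay apart from the 4 WT libraries for 30.6% of genes, against 2.86% by chance. Camera's adjusted p with its preset correlation and with an estimated correlation was 0.00193 and 0.553 for chemokines, 6.21e-13 and 0.353 for NF-kB response and 6.73e-05 and 0.353 for STAT3 response. The same pair of values was 6.21e-13 and 0.519 for interferon-stimulated genes, 1.97e-07 and 0.519 for acute phase proteins and 0.00318 and 0.635 for sterol biosynthesis. These were 0.00296 and 0.553 for Kupffer cell markers and 0.000107 and 0.625 for immediate early and heat shock. In all, 8 of 22 lists passed with the preset correlation and 0 with an estimated one, and 15 of 35 regroupings of the 8 libraries passed as many.

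By 36 h few HSC genes were called against WT, and Cfb and Cp were among them. Cfb, for complement factor B, rose from 507 ± 80.4 to 1722 ± 161 CPM (log2 fold change 1.76 ± 0.20 SE, adjusted p = 0.00261), and Cp rose from 439 ± 56.9 to 1223 ± 137 CPM (log2 fold change 1.48, adjusted p = 0.00172). All 4 libraries lay above every WT library for both. At 12 h Cfb stood at 1626 ± 547 CPM. Saa3 stood at 52.6 ± 18 CPM at 36 h against 0.144 ± 0.133 in WT (adjusted p = 0.0335). Its call rested on most libraries of both groups, with adjusted p values of 0.146 without HSC WT replicate 1, 0.137 without HSC WT replicate 2, 0.168 without HSC WT replicate 3, 0.171 without HSC WT replicate 4, 0.102 without HSC 36 h replicate 1, 0.0705 without HSC 36 h replicate 3, 0.0649 without HSC 36 h replicate 4. Col1a1 stood at 568 ± 111.9 CPM against 306 ± 29.3 (adjusted p = 0.0246, and 0.109 without HSC WT replicate 1, 0.0704 without HSC WT replicate 2, 0.127 without HSC WT replicate 3, 0.1 without HSC WT replicate 4, 0.0808 without HSC 36 h replicate 1, 0.0585 without HSC 36 h replicate 4). Ccl2 stood at 185 ± 133 CPM (log2 fold against WT 1.38, adjusted p = 0.348), Vcam1 at 826 ± 181.9 (adjusted p = 0.216) and Csf1 at 674 ± 67.8 (adjusted p = 0.676). edgeR called 18 of 12676 genes, 17 higher and 1 lower, with 868 at an unadjusted p under 0.05 and 124 by DESeq2. The count without 1 library was 3, 5, 2 and 2 for WT replicates 1 to 4 and 3, 33, 5 and 7 for 36 h replicates 1 to 4. Adjusted over the list alone, 19 of 30 interferon-stimulated genes and 12 of 23 acute phase genes were called, against 1 and 3 over all genes. Reads in no gene made up 6.66 to 7% in HSC WT libraries and 5.97 to 6.47% at 36 h, without overlap. Whether this difference moved the calls was not tested.

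Between 12 h and 36 h, HSC genes moved back towards WT. Spib, an Ets-family factor, fell from 5.29 ± 4.04 to 0.358 ± 0.22 CPM (log2 fold change -3.86 ± 0.65 SE, adjusted p = 0.000887). Ackr4 rose from 1.14 ± 0.953 to 11 ± 5.91 CPM and Crygs from 0.338 ± 0.343 to 6.21 ± 3.14 CPM (log2 fold change 4.17 ± 0.62 SE, adjusted p = 0.00043). edgeR called 3537 genes, 1632 higher and 1905 lower at 36 h. Of the 2150 genes that rose by 12 h, 1585 (73.7%) fell afterwards, and of the 1910 that fell, 1316 (68.9%) rose. Both comparisons share the 12 h libraries, so this overlap was also counted with the 12 h libraries divided between them, which left 488 to 881 genes for the first direction, against 73 to 250 under independence. Of 22 lists, 7 passed camera with its preset correlation at this step and 9 at 36 h against WT. With an estimated one, 0 and 0 passed (lowest adjusted p = 0.353 and 0.353), while 21 and 10 of 35 regroupings passed as many.

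LSECs also raised recruitment genes at 12 h. Ccl2 rose from 1.12 ± 0.35 to 66.9 ± 62.5 CPM (log2 fold change 5.90 ± 0.89 SE, adjusted p = 0.000931). Cxcl10 rose from 61.2 ± 16.4 to 442 ± 346 CPM (log2 fold change 2.85 ± 0.55 SE, adjusted p = 0.00357). Of the endothelial selectins, which let leukocytes roll, Sele (chromosome 1, 164039614 to 164058487) rose from 1.46 ± 0.755 to 53.7 ± 58.8 CPM (log2 fold 5.21). Its neighbour Selp (chromosome 1, 164115264 to 164150026) rose from 2.38 ± 1.42 to 28.6 ± 26.9 CPM (log2 fold 3.59). Vcam1 rose from 164 ± 21.2 to 611 ± 293 CPM (log2 fold change 1.89 ± 0.28 SE, adjusted p = 0.000931) and Icam1 from 205 ± 23.6 to 561 ± 300.2 CPM. The junction gene Jam2 rose from 865 ± 62.2 to 1626 ± 137 CPM and Madcam1, an addressin of gut venules, from 0.0258 ± 0.0173 to 2.63 ± 1.18 CPM. Csf1 rose from 301 ± 46.4 to 703 ± 148 CPM (log2 fold change 1.23 ± 0.17 SE, adjusted p = 0.000541). Gas6 fell from 689 ± 101 to 304 ± 103 CPM (log2 fold change -1.18 ± 0.22 SE, adjusted p = 0.00301). Dll4 had 535 ± 92.0 CPM in WT and 459.7 ± 80.8 at 12 h (adjusted p = 0.352). Hey1 fell from 4.70 ± 2.29 to 1.51 ± 0.162 CPM (log2 fold -1.64). Among chemokines, 7 of 13 rose (10 adjusted over the list alone). Among leukocyte adhesion molecules, 7 of 12 rose and 1 fell (9 and 1 adjusted over the list alone). Among niche ligands, 1 of 13 rose and 1 fell (1 and 1 adjusted over the list alone). Among Notch targets, 1 of 6 fell (1 adjusted over the list alone). Their median log2 fold was -0.13 and their mean 0.01. Camera's direction was down, but the list did not pass camera. Among BMP and SMAD targets, 2 of 9 fell (3 adjusted over the list alone).

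Some inflammatory, stress and vascular genes of LSECs rose at 12 h, and some endothelial identity genes fell. Tnfrsf9, the costimulatory receptor 4-1BB, rose from 0.303 ± 0.22 to 30.3 ± 31.7 CPM (log2 fold change 6.63 ± 0.83 SE, adjusted p = 0.000397). Tnfaip3, which curbs NF-kB, rose from 27.8 ± 5.44 to 113 ± 84.5 CPM and Lrg1, a vascular glycoprotein, from 16.9 ± 4.27 to 114 ± 82.3 CPM. Angptl4, an inhibitor of lipoprotein lipase, rose from 0.221 ± 0.0930 to 8.42 ± 7.25 CPM (log2 fold change 5.23 ± 0.81 SE, adjusted p = 0.00102). Pdgfa, a growth factor for mesenchymal cells, rose from 2.26 ± 0.628 to 9.26 ± 2.59 CPM and Hgf, the growth factor for hepatocytes, from 92.4 ± 41.8 to 208 ± 42.0 CPM. Cdkn1a, the p21 cell cycle inhibitor, rose from 80.4 ± 36.1 to 244 ± 71.4 CPM and Hmox1 from 72.1 ± 14.4 to 204 ± 50.9 CPM. Isg15, a ubiquitin-like interferon product, rose from 25.2 ± 8.23 to 79.1 ± 49.8 CPM and Zbp1 from 4.36 ± 1.68 to 25.9 ± 25.0 CPM. Kdr, the VEGF receptor, fell from 6301 ± 642 to 4227 ± 659 CPM (log2 fold change -0.58 ± 0.13 SE, adjusted p = 0.00919). Itga8, an integrin chain, fell from 337 ± 51.3 to 80.4 ± 39.9 CPM and Gpr155, a cholesterol-sensing membrane protein, from 293 ± 48.7 to 67.9 ± 20.7 CPM. Klhdc8a, a kelch-domain protein, fell from 15.3 ± 4.06 to 2.38 ± 1.46 CPM (log2 fold change -2.69 ± 0.37 SE, adjusted p = 0.00057) and Khk, which phosphorylates fructose, from 39.1 ± 9.25 to 9.75 ± 3.19 CPM. Among NF-kB response genes, 8 of 23 rose (8 adjusted over the list alone). Among STAT3 response genes, 5 of 15 rose and 1 fell (5 and 1 adjusted over the list alone). Among interferon-stimulated genes, 8 of 29 rose (16 adjusted over the list alone). Among acute phase proteins, 11 of 23 rose and 0 fell (15 and 1 adjusted over the list alone). Among p53 targets, 4 of 11 rose and 1 fell (4 and 1 adjusted over the list alone). Among immediate early and heat shock genes, 4 of 21 rose (4 adjusted over the list alone). Among angiocrine growth factors, 4 of 12 rose and 1 fell (5 and 1 adjusted over the list alone). Among iron handling genes, 5 of 14 rose and 1 fell (5 and 1 adjusted over the list alone). Among LSEC identity genes, 2 of 20 rose and 7 fell (2 and 10 adjusted over the list alone). The summed level of the immediate early and heat shock genes ran from 4598 to 25786 CPM in WT and 9558 to 29904 at 12 h, highest in the replicates that stood high in HSCs (WT 2 and 12 h 1 and 4). These sums follow the replicate number as well as the group, and an effect of the preparation is not separated from one of the toxin.

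The remaining lists of LSECs at 12 h hold markers of other cells, metabolic genes and cell cycle genes. Lyz2, the lysozyme of myeloid cells, had 7.31 ± 2.19 CPM in WT and 10.3 ± 4.54 at 12 h (adjusted p = 0.533). Among Kupffer cell markers, 5 of 13 fell and 0 rose (6 and 1 adjusted over the list alone). Among monocyte and neutrophil markers, 2 of 11 rose (4 adjusted over the list alone). Among erythroid and platelet markers, 1 of 4 rose (3 adjusted over the list alone). Lymphocyte markers had 0 of 7 called by edgeR (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by DESeq2). Cholangiocyte markers had 0 of 1 called by edgeR (1 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by DESeq2). Hepatocyte identity had 0 of 18 called by edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by DESeq2). The median log2 fold was -0.01 and the mean 0.02. Camera's direction was up, but the list did not pass camera. Among stellate identity genes, 1 of 17 rose and 1 fell (1 and 1 adjusted over the list alone). Among stellate activation genes, 2 of 14 rose (2 adjusted over the list alone). Among sterol biosynthesis genes, 2 of 24 fell (0 adjusted over the list alone). Among LXR targets, 1 of 12 rose and 1 fell (2 and 2 adjusted over the list alone). Their median log2 fold was -0.10 and their mean 0.01. Camera's direction was up, but the list did not pass camera. Among bile acid and drug metabolism genes, 1 of 19 rose and 1 fell (1 and 1 adjusted over the list alone). Cell cycle genes had 0 of 28 called by edgeR (0 adjusted over the list alone, 7 at an unadjusted p under 0.05, 3 by DESeq2).

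Across 12286 genes tested in LSECs, edgeR called 2241 at 12 h, 1197 higher and 1044 lower, of which 326 and 217 changed at least 2-fold. Libraries at 12 h lay apart from WT libraries for 22.8% of genes, against 2.86% by chance. Reads in no gene made up 6.63 to 7.43% in LSEC WT libraries and 4.9 to 6.39% at 12 h. These ranges do not overlap, and whether this difference moved the calls was not tested. Camera's adjusted p with its preset correlation and with an estimated correlation was 0.000635 and 0.353 for chemokines, 6.41e-05 and 0.353 for leukocyte adhesion molecules and 7.82e-05 and 0.519 for NF-kB response. The same pair of values was 0.00193 and 0.519 for STAT3 response, 5.19e-06 and 0.635 for interferon-stimulated genes and 0.000323 and 0.635 for acute phase proteins. These were 0.000663 and 0.519 for LSEC identity, 0.0166 and 0.635 for Kupffer cell markers and 0.0262 and 0.786 for cell cycle. They were 0.000204 and 0.635 for immediate early and heat shock and 0.0071 and 0.353 for p53 targets. Of 24 lists, 11 passed with the preset correlation and 0 with an estimated one, and 10 of 35 regroupings passed as many.

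At 36 h no LSEC gene remained past the threshold against WT. Ccl2 stood at 5.50 ± 7.03 CPM against 1.12 ± 0.35 in WT (log2 fold 2.29 ± 0.85 SE, adjusted p = 0.378). Csf1 stood at 458 ± 68.3 against 301 ± 46.4 (log2 fold 0.61, adjusted p = 0.308). Cxcl10 stood at 158 ± 73.3 (adjusted p = 0.391) and Sele at 3.61 ± 4.06 (adjusted p = 0.608). Dcn, a proteoglycan of stellate cells, stood at 42.0 ± 54.9 CPM against 5.63 ± 1.18, with 123 CPM in replicate 4. edgeR called 0 of 12286 genes, with 1288 at an unadjusted p under 0.05, a lowest adjusted p of 0.161 and 109 called by DESeq2. Leaving out 36 h replicate 1 or 36 h replicate 4 gave 1 call. Adjusted over the list alone, edgeR called 18 of 28 cell cycle genes, 14 of 17 stellate identity genes, 13 of 23 acute phase genes and 9 of 29 interferon-stimulated genes, and 0 of each over all genes. Replicate 4 at 36 h stood highest for the summed cell cycle genes (1368 CPM, with WT at 470.2 to 749), the stellate identity genes (1015 CPM, with WT at 381 to 544), the acute phase genes (1083 CPM, with WT at 269 to 425) and the hepatocyte identity genes (609 CPM, with WT at 56.5 to 237). For cell cycle genes 36 h replicates 1 and 3 lay within the WT range, and for acute phase genes 36 h replicates 1 and 2.

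Between 12 h and 36 h, Ch25h, which makes 25-hydroxycholesterol, fell from 36.6 ± 22.6 to 1.46 ± 0.900 CPM (log2 fold change -4.65 ± 0.54 SE, adjusted p = 0.000178). Prf1, for perforin, fell from 5.09 ± 1.79 to 0.245 ± 0.308 CPM and Tnfrsf9 from 30.3 ± 31.7 to 1.64 ± 1.28 CPM in LSECs. Gna14, a G protein subunit, rose from 13.7 ± 5.16 to 78.7 ± 26.0 CPM (log2 fold change 2.53 ± 0.28 SE, adjusted p = 0.000178). Ccbe1, a lymphangiogenic factor, rose from 0.515 ± 0.204 to 6.50 ± 2.35 CPM and Klhdc8a from 2.38 ± 1.46 to 19.5 ± 6.85 CPM. edgeR called 2623 genes, 1299 higher and 1324 lower at 36 h. Of the 1197 genes that rose by 12 h, 916 (76.5%) fell afterwards, and of the 1044 that fell, 769 (73.7%) rose. With the 12 h libraries divided between the comparisons, 259 to 374 genes rose and fell, against 20 to 78 under independence. Of 24 lists, 9 passed camera with its preset correlation at this step and 9 at 36 h against WT. With an estimated one, 0 and 0 passed (lowest adjusted p = 0.353 and 0.353), while 19 and 15 of 35 regroupings passed as many.

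Hepatocytes showed no gene past the threshold at 12 h or 36 h in the unpaired fit. With replicate number as a block over all hepatocyte libraries, 5 genes were called at 36 h. That block also covers the 12 h libraries, whose pairs did not all pass the limit of 0.1. A fit with pairs of the WT and 36 h libraries alone was not run. The count of 0 at 36 h thus leaves out a pairing that passed the limit. Icam1 had 5.13 ± 0.694 CPM in WT, 11.3 ± 5.26 at 12 h and 7.03 ± 2.68 at 36 h (log2 fold at 12 h 1.14 ± 0.31 SE, adjusted p = 0.591). Csf1 had 2.95 ± 0.759, 4.21 ± 1.54 and 3.92 ± 1.68 CPM, and Cxcl10 1.74 ± 1.03, 2.05 ± 0.633 and 2.39 ± 0.867 CPM. The cholesterol exporter gene Abca1 had 122 ± 65.0, 135 ± 46.5 and 104 ± 73.5 CPM. Alb had 32817 ± 6721 CPM in WT and 35810.0 ± 9778 at 12 h. Csf1r, the CSF1 receptor of macrophages, had 3.01 ± 2.47, 0.142 ± 0.167 and 0.473 ± 0.167 CPM (adjusted p = 0.377 at 12 h and 0.456 at 36 h). Of 11326 genes, edgeR called 0 at 12 h, 0 at 36 h and 0 between 12 h and 36 h, with 453, 564 and 725 at an unadjusted p under 0.05 and 47, 59 and 24 called by DESeq2. Adjusted over the list alone, edgeR called 8 of 24 acute phase genes at 12 h, and 9 of 24 acute phase and 6 of 27 cell cycle genes between 12 h and 36 h. The summed acute phase level at 12 h was highest in replicate 2 (64100.0 CPM, with WT at 27689 to 34604), and 12 h replicates 1 and 3 lay within that range. Of 17 lists, 6, 3 and 5 passed camera with its preset correlation. With an estimated one, 0, 0 and 0 passed (lowest adjusted p = 0.353, 0.353 and 0.353), while 14, 29 and 24 of 35 regroupings passed as many.

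The hepatocyte libraries split on their Malat1 level across the groups. Malat1, a nuclear long noncoding RNA, stood at 242 to 479 CPM in 5 libraries (WT replicates 1 and 2, 12 h replicate 1, and 36 h replicates 1 and 2) and at 24.8 to 44.9 CPM in the other 7. A fit of this split, chosen after the data were seen, called 4883 of 11326 genes. With the split as a term in the fit, 2 genes were called at 12 h and 10 at 36 h. Id3, a target of BMP signalling, was called at both, with log2 folds of 1.91 ± 0.20 SE (adjusted p = 0.00367) and 1.88 ± 0.20 SE (adjusted p = 0.00171). Without the term Id3 had adjusted p = 0.912 and 0.438, and its level was 27.3 ± 18.8 CPM in WT, 69.5 ± 18.9 at 12 h and 89.0 ± 35.3 at 36 h. Id3 was chosen after its values were seen. The pairing by replicate number at 36 h follows the Malat1 split.

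**Figure D4:**
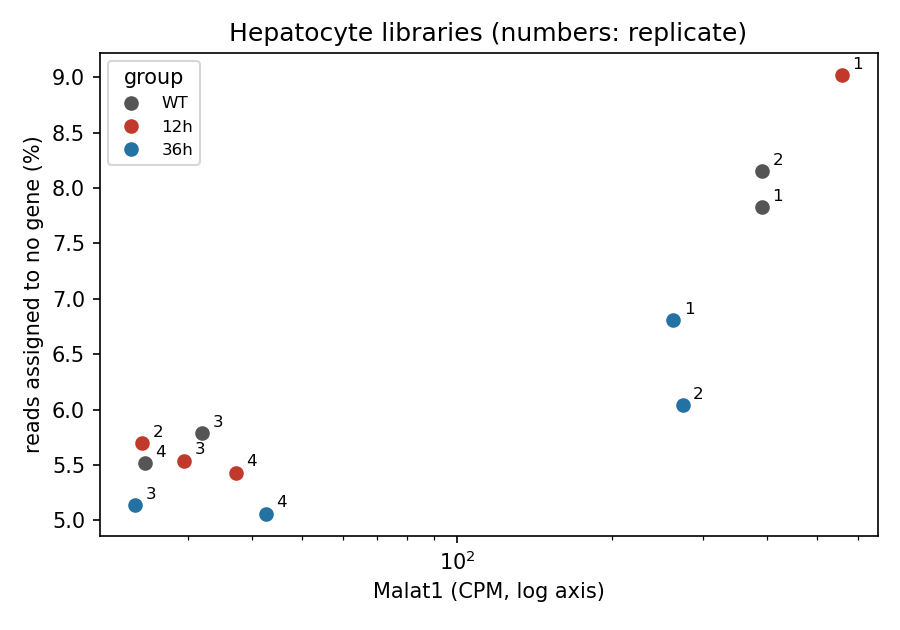
Malat1 level (CPM on plain library totals, log axis) against the share of reads in no gene (percent) for the 12 hepatocyte libraries, coloured by group and labelled by replicate. The 5 libraries with high Malat1 have 7.57 ± 1.17% of reads in no gene, against 5.45 ± 0.271% (SD) in the other 7.

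HSCs and LSECs shared much of their answer at 12 h. Of 11595 genes tested in both, 780 rose in both, against 198 under independence, 499 fell in both, against 134, and 20 and 28 went opposite ways, against 168 and 158. A test of the difference itself called 229 of 14104 genes, 116 with the larger log2 fold in HSCs and 113 in LSECs. These counts treat HSC and LSEC libraries as independent, although libraries of 1 number deviate together. A fit of the HSC and LSEC libraries alone, with a term for animals that such libraries would share, called 797 genes. It was chosen after the data were seen. It differs from the first fit in its libraries and in the term, and which of these raised the count was not tested. Gch1, which starts tetrahydrobiopterin synthesis, went from 0.624 ± 0.307 to 21 ± 11.4 CPM in HSCs and from 36.8 ± 2.64 to 44.7 ± 10.9 CPM in LSECs (difference in log2 fold 4.79 ± 0.49 SE, adjusted p = 7.61e-07). Klhdc8a went from 0.170 ± 0.149 to 0.928 ± 0.290 CPM in HSCs and down in LSECs (difference 5.15 ± 0.64 SE, adjusted p = 8.14e-06). C1qb, a chain of complement C1q, went from 3.02 ± 2.06 to 0.117 ± 0.0737 CPM in HSCs and from 14 ± 5.24 to 37.2 ± 14.3 CPM in LSECs (difference -6.04 ± 1.16 SE, adjusted p = 0.00298). At 36 h edgeR called 0 genes, with 567 at an unadjusted p under 0.05, a lowest adjusted p of 0.0683 and 13 called by DESeq2. Without LSEC 36 h replicate 1 it called 31.

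Against hepatocytes, 1298 genes answered differently in HSCs at 12 h and 503 in LSECs. Saa3 went from 0.144 ± 0.133 to 162.9 ± 253 CPM in HSCs and from 2.83 ± 1.48 to 13.8 ± 15.5 CPM in hepatocytes (difference 7.81 ± 1.64 SE, adjusted p = 0.00331). Angptl4 went from 0.221 ± 0.0930 to 8.42 ± 7.25 CPM in LSECs and from 179 ± 29.3 to 51.6 ± 21.9 CPM in hepatocytes (difference 6.97 ± 1.25 SE, adjusted p = 0.00278). Rcor3, a corepressor subunit, was the 1 gene called at 36 h in each comparison (differences -1.23 and -1.28, adjusted p = 0.035 and 0.0183). It stood at 3.36 ± 0.692 CPM in hepatocyte WT libraries, 7.02 ± 0.958 at 36 h, 24.1 ± 3.50 and 21.7 ± 2.20 in HSCs and 30.9 ± 1.61 and 26.8 ± 5.38 in LSECs. Its call against HSCs ended for 10 libraries, with adjusted p values of 0.138 without HSC WT replicate 1, 0.162 without HSC WT replicate 3, 0.0725 without HSC 36 h replicate 1, 0.0741 without HSC 36 h replicate 2, 0.151 without HSC 36 h replicate 4, 0.135 without hepatocyte WT replicate 2, 0.0541 without hepatocyte WT replicate 3, 0.0538 without hepatocyte 36 h replicate 2, 0.0856 without hepatocyte 36 h replicate 3, 0.0784 without hepatocyte 36 h replicate 4. It also ended with RLE scaling (0.0561) and without the filter on low counts (0.052). Against LSECs it ended for 3, with 0.0631 without LSEC WT replicate 2, 0.0549 without LSEC 36 h replicate 4, 0.0667 without hepatocyte 36 h replicate 3. The 503 genes of LSECs against hepatocytes became 250 without LSEC WT replicate 1, 309 without LSEC WT replicate 3, 322 without LSEC WT replicate 4, 243 without LSEC 12 h replicate 3, 251 without hepatocyte WT replicate 1, 302 without hepatocyte WT replicate 2, 309 without hepatocyte 12 h replicate 3 and 265 without hepatocyte 12 h replicate 4. The 1298 of HSCs became 688 without HSC 12 h replicate 3. At 36 h, genes that differed between HSCs and hepatocytes numbered 2 without hepatocyte WT replicate 1, 2 without hepatocyte WT replicate 3, 5 without hepatocyte WT replicate 4 and 3 without hepatocyte 36 h replicate 1. At 36 h, genes that differed between LSECs and hepatocytes numbered 3 without LSEC WT replicate 1, 2 without LSEC WT replicate 3, 9 without LSEC 36 h replicate 1, 2 without LSEC 36 h replicate 2, 2 without hepatocyte WT replicate 1, 2 without hepatocyte WT replicate 2, 4 without hepatocyte WT replicate 3, 4 without hepatocyte WT replicate 4, 2 without hepatocyte 36 h replicate 1 and 2 without hepatocyte 36 h replicate 4.

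**Figure D5:**
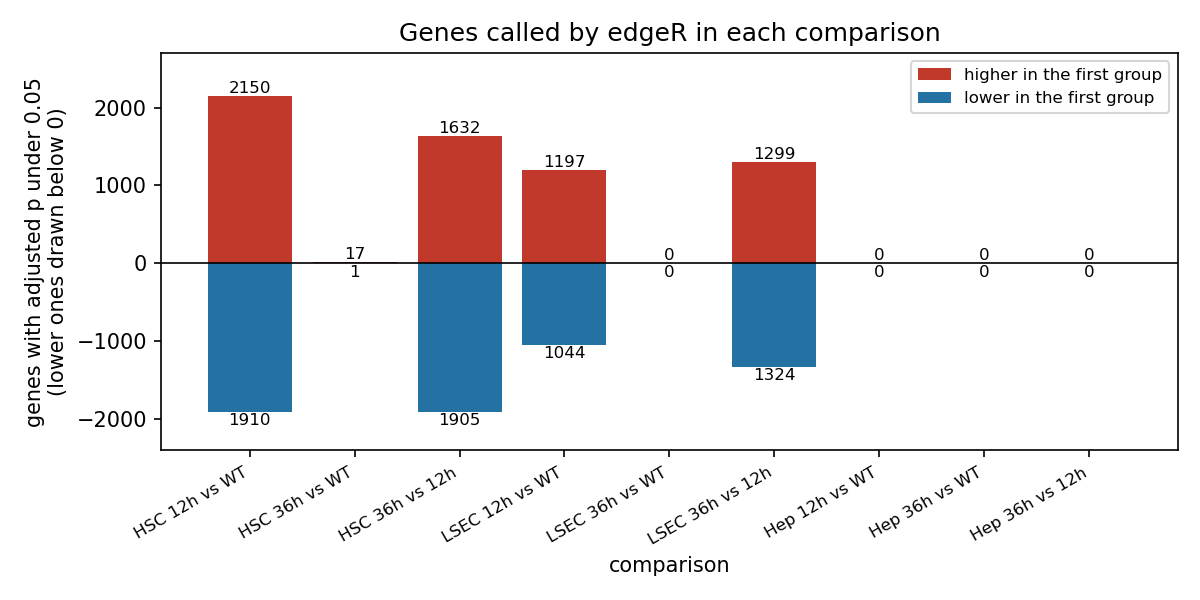
Genes called higher (up) and lower (down) by edgeR in each of the 9 comparisons within a cell type, as counts on a linear axis. HSCs at 12 h have 2150 and 1910, LSECs at 12 h 1197 and 1044, and hepatocytes 0 in every comparison, all without pairing.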

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

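Among the tests here, those of gene length and sequencing depth were set before their results, while the Malat1 split, the tests of nuclear RNA and of RNA from other cells, the single-library test and the regroupings were chosen only after the result was seen.

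A library far from the other 3 of its group was found in 35 of 545 groups of values, where chance alone gives about 27. Hepatocyte WT replicate 4 had 30.3 against 27.1 to 27.6 in counts (units of 1000000), and hepatocyte 12 h replicate 1 had 9.02% of reads in no gene against 5.43 to 5.7%. List scores are the mean log2 CPM of the members of a list. HSC WT replicate 1 had a score of 1.92 for chemokines against 2.11 to 2.14. LSEC 36 h replicate 4 had a score of 4.2 for macrophage niche ligands against 3.64 to 3.73. HSC 36 h replicate 3 had a score of 3.54 for Notch targets against 3.31 to 3.33. HSC WT replicate 2 had a score of 3.99 for NF-kB response against 3.65 to 3.66. HSC 12 h replicate 2 had a score of 6.4 for STAT3 response against 6.98 to 7.1. LSEC 12 h replicate 2 had a score of 6.25 for STAT3 response against 6.81 to 6.91. Hepatocyte 36 h replicate 1 had a score of 4.54 for STAT3 response against 4.31 to 4.33. LSEC 12 h replicate 3 had a score of 4.16 for sterol biosynthesis against 3.83 to 3.84. Hepatocyte 12 h replicate 1 had a score of 7.43 for sterol biosynthesis against 7.81 to 7.86, 6.18 for LXR targets against 6.88 to 7.02 and 7.11 for iron handling against 7.54 to 7.58. HSC WT replicate 3 had a score of 4.56 for iron handling against 4.35 to 4.37. HSC 12 h replicate 3 had a score of 3.71 for hepatocyte identity against 2.69 to 2.86. HSC 36 h replicate 4 had a score of 1.32 for Kupffer cell markers against 0.116 to 0.237. Hepatocyte 12 h replicate 2 had a score of 1.1 for cell cycle against 0.256 to 0.397. By gene, the following levels stood apart. HSC WT replicate 1 had 19.6 CPM of Ackr4 against 9.95 to 11.2 and 46.4 CPM of Ccl2 against 76.2 to 82.7. Hepatocyte 12 h replicate 2 had 19.2 CPM of Angptl4 against 57.6 to 66.6 and 19.2 CPM of Icam1 against 8.18 to 9.11. HSC 36 h replicate 4 had 2.52 CPM of C1qb against 0.340 to 0.423, 5.43 CPM of Cd5l against 0.0681 to 0.317, 3944 CPM of Colec11 against 4684 to 4832 and 1.65 CPM of Crygs against 6.74 to 8.56. LSEC 36 h replicate 4 had 16 CPM of Ccl2 against 1.52 to 2.37 and 1.60 CPM of Madcam1 against 0.135 to 0.203. HSC WT replicate 2 had 627 CPM of Cfb against 454 to 475. HSC 36 h replicate 1 had 1964 CPM of Cfb against 1626 to 1653. LSEC WT replicate 2 had 85.6 CPM of Cxcl10 against 51.3 to 55.6. HSC 36 h replicate 2 had 37.5 CPM of Dll4 against 51.1 to 54.1. Hepatocyte 12 h replicate 1 had 97.8 CPM of Id3 against 59.0 to 61.2. LSEC 12 h replicate 1 had 25.9 CPM of Rcor3 against 21.8 to 22.2 and 239 CPM of Tnfaip3 against 61.9 to 77.8. HSC 12 h replicate 2 had 1.19 CPM of Sptssb against 0.218 to 0.326.

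The response to the toxin differed between cell types by a test of the difference itself for 229 genes between HSCs and LSECs at 12 h, 1298 between HSCs and hepatocytes at 12 h, 503 between LSECs and hepatocytes at 12 h. At 36 h it differed for 1 gene each between hepatocytes and HSCs and between hepatocytes and LSECs, Rcor3 (log2 difference -1.23 and -1.28). The largest log2 differences of HSCs from LSECs were in Klhdc8a (5.15), Trib3 (5.07), Tcf23 (5.0), Gch1 (4.79), Traf1 (4.51), C5ar1 (-6.74), C1qb (-6.04), P2rx1 (-5.86), Gp1ba (-5.41) and C1qa (-5.21). HSCs differed most from hepatocytes in Sdc3 (8.45), Tmem132e (8.09), Saa3 (7.81), Fat4 (7.42), Itga9 (7.34), Slc52a3 (-9.27), Csdc2 (-7.98), Pde1c (-6.92), Podxl (-6.71) and Kazn (-6.02). LSECs differed most from hepatocytes in C1qa (9.46), Sdc3 (8.87), C1qc (8.57), C1qb (6.99), Angptl4 (6.97), Csdc2 (-9.04), Kazn (-6.04), Ksr1 (-6.02), Podxl (-5.93) and Dsel (-5.56). Values of genes with libraries near 0, such as Sdc3, Itga9, Kazn and the C1q genes in hepatocytes, depend on the prior count and are no bounds. Sdc3, a heparan sulfate proteoglycan, had 1.80 ± 1.96 CPM in hepatocyte WT libraries and no count at 12 h, at least 72.7-fold lower. Some of these calls ended when 1 of the 16 libraries was left out. Between HSCs and LSECs these were Trib3 at 0.0686 without HSC 12 h replicate 3, P2rx1 at 0.089 without LSEC 12 h replicate 3. Others were Tcf23 without any of 14 libraries (adjusted p of 0.0513 to 0.131, highest without LSEC WT replicate 1), C5ar1 without any of 12 libraries (adjusted p of 0.0508 to 1, highest without HSC WT replicate 3), C1qa without any of 6 libraries (adjusted p of 0.0508 to 0.0869, highest without HSC WT replicate 3). Between HSCs and hepatocytes they were Tmem132e at 1 without hepatocyte WT replicate 4, Fat4 at 0.148 without hepatocyte WT replicate 2, Pde1c at 0.175 without hepatocyte 12 h replicate 1, Podxl at 0.0627 without hepatocyte 12 h replicate 1. Others were Slc52a3 without any of 11 libraries (adjusted p of 0.0548 to 1, highest without hepatocyte 12 h replicate 2). Between LSECs and hepatocytes they were Csdc2 without any of 12 libraries (adjusted p of 0.0547 to 0.19, highest without LSEC WT replicate 4), Podxl without any of 13 libraries (adjusted p of 0.0506 to 0.155, highest without hepatocyte 12 h replicate 1), Dsel without any of 13 libraries (adjusted p of 0.0533 to 0.173, highest without hepatocyte 12 h replicate 4). Calls also ended in other fits. Rcor3 against HSCs at 36 h ended with RLE scaling (adjusted p = 0.0561) and without the filter on low counts (0.052). At 12 h, with the replicate block these were Tcf23 at 0.0665, C5ar1 at 0.0527 between HSCs and LSECs and Dsel at 0.0783 between LSECs and hepatocytes, and with the animal term Trib3 at 0.059, Tcf23 at 0.095 and C5ar1 at 0.128 between HSCs and LSECs. Without the filter on low counts they were Tcf23 at 0.055 between HSCs and LSECs, Slc52a3 at 0.0552 between HSCs and hepatocytes, Csdc2 at 0.0555, Podxl at 0.0509 and Dsel at 0.0531 between LSECs and hepatocytes, and with RLE scaling Csdc2 at 0.0505 between LSECs and hepatocytes.

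Regroupings of the libraries were set against these counts. As many genes as in the real grouping came from 3 of 100 drawn regroupings for HSCs and LSECs at 12 h, 2 of 100 for HSCs and hepatocytes and 2 of 100 for LSECs and hepatocytes, the real one included. Each share is under the 0.05 set for this test, without adjustment over the counts tested. For HSCs and LSECs the draws moved each cell type on its own, although their libraries of 1 number deviate together. Chance is thus made unlikely for these 3 counts but is not excluded. The highest of the other regroupings called 3196, 1597 and 1406 genes against 229, 1298 and 503 in the real grouping. The largest, for HSCs and LSECs, came from a regrouping that mostly exchanges WT and 12 h in HSCs (libraries left in place minus libraries exchanged -6) and not in LSECs (4), where a difference of responses becomes a sum of them. The groups themselves can thus give such a count. At 36 h, 31 of 100 and 33 of 100 regroupings called at least 1 gene (highest 675 and 1926), so chance is not excluded for the 1 gene called in each comparison with hepatocytes. What raised the counts of those regroupings was not tested. A count of 0 is reached by every regrouping, 100 of 100 for HSCs and LSECs at 36 h (highest 1415), so that count was not tested.

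Hepatocyte libraries split by Malat1 into 5 and 7, with 2547 genes higher and 2336 lower in the libraries rich in Malat1. Among them were 21 of 24 sterol biosynthesis genes and 11 of 13 LXR targets lower and 16 of 29 interferon-stimulated genes higher. Gene length is excluded as the whole cause, since 4472 genes were called after a length correction, 3729 of them among the 4720 called in the same direction before it. The correction took the rank correlation with length from -0.34 to -0.0039. Depth is excluded, since 4863 genes, 4795 of them called in the same direction before, were called with all libraries thinned to 26.2 (in units of 1000000 counts). Of 12 tested identity genes of stellate or sinusoidal cells, 1 was higher and 1 lower. This argues against RNA of these cells as the main cause but does not exclude a share of it, since most members were not tested. The summed stellate identity genes ran from 21.1 to 40.8 CPM in the libraries rich in Malat1 and from 14.2 to 33.4 in the others. The summed LSEC identity genes ran from 56.7 to 91.8 and from 86.8 to 175 CPM. A larger share of nuclear RNA is a candidate explanation, since reads in no gene were more frequent in those libraries (7.57 ± 1.17% against 5.45 ± 0.271%, 2-sided exact permutation p = 0.00126 over 792 splits). The split crosses all 3 groups, so no biological explanation was tested.

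C1qb differed between HSCs and LSECs at 12 h, falling in HSCs from 3.02 ± 2.06 to 0.117 ± 0.0737 CPM and standing at 14 ± 5.24 CPM in LSEC WT libraries and 37.2 ± 14.3 at 12 h. The other 9 tested Kupffer markers had a median log2 fold of -2.27 in LSECs at 12 h (-2.27 with the 1 member without counts at its bound). edgeR called 5 of them lower and 0 higher. These values argue against a larger share of Kupffer cell RNA of unchanged makeup as the source of the C1qb level. Kupffer cells whose C1q RNA rose against the other markers are not excluded by them. Monocytes or neutrophils in the LSEC preparation stay open, because the myeloid marker Lyz2 had a log2 fold of 0.495 and was not called, and so does a change in expression by LSECs, which was not tested.

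Acute phase genes rose in HSCs at 12 h, 19 of 23, with a median log2 fold of 2.40. A larger share of hepatocyte RNA is excluded as the cause, since 19 hepatocyte identity genes had a median log2 fold of 0.106 with a median absolute deviation of 0.276. A steady share from hepatocytes with raised acute phase genes would not move the identity genes. At 12 h the acute phase and hepatocyte identity genes summed to 24804 ± 1879 and 404 ± 102 CPM in HSCs. In hepatocytes these sums were 41411 ± 15139 and 94997 ± 16962 CPM, which argues against such a source of the summed level. A single library is excluded too, since 17 of these 19 stayed called without HSC 12 h replicate 3, the library with the highest score for hepatocyte identity. Without any other of the 8 WT and 12 h libraries, 17 to 19 stayed called. A response of HSCs is left as a hypothesis, and the toxin and the depletion cannot be separated by the groups analysed here.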

How the results depend on the processing

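The fits with the Malat1 split, with an animal term and without the libraries that stand apart (replicate 3 at 12 h and replicate 4 at 36 h) were chosen only after the data were seen. No named gene that was called in the text or in an alternative had opposite directions in them. Changes of direction in genes called in neither were not counted. For values outside a factor of 1.5 of the count in the text, or past 0 where it was 0, the cause was not tested.

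HSCs at 36 h against WT had 18 calls, 124 with DESeq2, 10 with the replicate block and 45 with only the 2 groups. LSECs at 36 h had 109 with DESeq2, 5 with the block, 2 with only the 2 groups and 1 without the libraries that stand apart, against 0. Hepatocytes, at 0 in each comparison, had 47, 59 and 24 with DESeq2 at 12 h, at 36 h and between them, 1, 5 and 3 with the block. They had 2 and 10 at 12 h and 36 h with the Malat1 split as a term, 6 and 10 in the libraries low in Malat1 and 20 at 36 h in those rich in it. DESeq2 made more false calls than edgeR on simulated data (8.72 to 22.1% against 0.794 to 7.87%).

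In the other 8 comparisons within a cell type, at least 1 pair of libraries with the same number had a correlation of -0.22 to 0.07, under the limit for pairing. Whether such libraries share more than a number is left open, and the block is a hint from the data. It moved no other count of genes within a cell type by over 1.5 times.

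HSCs and LSECs differed at 12 h in 229 genes, 466 with DESeq2 and 349 with the block, and at 36 h in 13 with DESeq2. The animal term, in a fit without hepatocyte libraries, gave 797 at 12 h. HSCs and hepatocytes differed at 36 h in 1 gene, 0 with RLE scaling, 0 without the filter, 62 with DESeq2, 11 with the block and 6 with the split term. LSECs and hepatocytes differed at 12 h in 503, 1008 with DESeq2 and 915 with the block, and at 36 h in 1, 87 with DESeq2, 18 with the block and 6 with the split term.

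Lists past camera's threshold numbered 8, 9, 7 in HSCs (12 h, 36 h and between them), 11, 9, 9 in LSECs and 6, 3, 5 in hepatocytes, and 0 in all 9 with an estimated correlation. The test fry passed 9, 2 and 6 in HSCs, 6, 0 and 4 in LSECs and 0, 0 and 0 in hepatocytes.

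Leaving out 1 library gave 3146 to 4064 genes in HSCs at 12 h, 2 to 33 at 36 h, 2622 to 3600 between them, 1539 to 2349 genes in LSECs at 12 h, 0 to 1 at 36 h, 1784 to 2623 between them, 0 genes in hepatocytes at 12 h, 0 at 36 h, 0 between them. Responses differed in 155 to 249 genes between HSCs and LSECs at 12 h and 0 to 31 at 36 h, 688 to 1483 and 0 to 5 between HSCs and hepatocytes, and 243 to 581 and 0 to 9 between LSECs and hepatocytes. Lists numbered 8, 8 to 11, 7 to 9 in HSCs, 10 to 13, 6 to 10, 7 to 10 in LSECs and 6 to 8, 3 to 5, 4 to 7 in hepatocytes. Genes highest in 1 cell type numbered 2227 to 2458 in HSCs, 2321 to 2587 in LSECs and 3900 to 3964 in hepatocytes.

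Named genes kept their side of the threshold in 388 tests with RLE scaling and changed it in 2. With no filter 380 kept it and 10 lost a call. With DESeq2 382 kept it and 8 gained one. With the block 369 kept it, 4 gained and 17 lost one, and with only the 2 groups 343 kept it, 1 gained and 7 lost one. Over all fits without 1 library 3080 kept it, 9 gained and 287 lost one. With the animal term 7 kept it and 3 lost a call, and without the libraries that stand apart 296 kept it, 1 gained and 13 lost one. With the Malat1 split as a term 68 kept it and 0 lost one. In libraries low in Malat1 46 kept it, and in those rich in it 22 kept it and 1 gained one. At this depth and spread edgeR recovered 4.48% of simulated 1.5-fold changes in hepatocytes at 12 h, so changes of that size were mostly not detectable there.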

Other observations

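The tests of shared livers and of regroupings were chosen only after the result was seen.

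All 35 divisions of the 8 libraries of a comparison into groups of 4 were fitted. For genes, 1, 1 and 1 of 35 gave as many calls in HSCs at 12 h, at 36 h and between them. The real counts were 4060, 18 and 3537, and the highest of the others 0, 0 and 0. It was 1 and 1 in LSECs at 12 h and between them (real 2241 and 2623, highest of the others 17 and 1). Chance is thus made unlikely for these counts of HSCs and LSECs. It is not excluded, since 1 of 35 is the smallest share the divisions allow, without adjustment over the counts tested. Where the real count was 0, every division reaches it, 35 of 35 in LSECs at 36 h (highest of the others 0) and 35, 35 and 35 in hepatocytes, so these counts were not tested. The highest of the others in hepatocytes were 1, 3805 and 0 genes, and the division with 3805 follows the Malat1 split and parts no pair of libraries with the same number. The highest among the others that part all 4 pairs called 0. For genes highest in 1 cell type of WT libraries, 1, 1 and 1 of 100 drawn regroupings gave as many (highest of the others 0, 0 and 0). These regroupings mix cell types within a group, so few calls could come from them and the test adds little to these counts.

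Counts of lists past camera's preset threshold were no larger than regroupings give. As many lists came from 15, 10, 21 of 35 divisions in HSCs at 12 h, at 36 h and between them (real 8, 9, 7, highest of the others 12, 12, 13). They came from 10, 15, 19 in LSECs (real 11, 9, 9, highest of the others 13, 12, 14). In hepatocytes they came from 14, 29, 24 (real 6, 3, 5, highest of the others 9, 8, 8). Chance is not excluded for any of these 9 counts, and the calls of single genes within the lists carry the result.

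HSC and LSEC libraries with the same number may come from the same livers. Their deviations from the group mean had a mean correlation across genes of 0.197 over 14104 genes, against -0.0651 for different numbers of a group, and the 1-sided exact permutation p was 0.000145 over 13824 assignments (adjusted 0.000435). With the 11595 genes tested in both cell types the means were 0.274 and -0.0905, and with 10164 genes tested in all 3 they were 0.321 and -0.106, with exact p = 7.23e-05, the smallest that the assignments allow. Genes are not independent replicates. The lowest correlation of a same-numbered pair was 0.031, 0.058 and 0.11 with the 3 gene sets, and 10, 11 and 11 of 12 libraries correlated best with their own number. Every pair passed the limit of 0.1 that was set for pairing only with the genes tested in all 3 cell types, and the numbers were not used as pairs in the text. The same test for hepatocytes and HSCs gave exact p = 0.947 with a mean of -0.029, and shows no sign of shared livers there, in libraries whose deviations follow the Malat1 split.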
